A study of Arabidopsis thaliana with 15 samples.

How the data were processed

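The deposited values were log2 expression values of probe sets on Affymetrix ATH1 arrays, 1 column per array. Per the submitters' processing notes, they came from RMA in the R package affy 1.36.0; RMA corrects background, normalises by quantiles across the arrays and summarises each probe set. Whether any filter was applied is not stated. Per the labels' protocols, RNA was extracted with a column kit, and 2 µg of total RNA per sample was spiked with bacterial control transcripts before cDNA synthesis. It was then amplified to biotin-labelled antisense cRNA. The values were used as deposited, with no further scaling in the fit the report gives.

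The table held 22810 probe sets. The 64 control probe sets were left out of all tests, so that 22746 were tested. A probe set was named where the platform annotation gave it exactly 1 gene: 13513 probe sets named 1 gene, 503 named several and 8730 named none. They stood for 13356 different genes, matched by their Entrez identifiers to RefSeq locus tags. Of the named probe sets, 11885 carried only a locus tag and no other symbol, and such genes appear by their tag. For the 146 genes with more than 1 probe set, the probe set with the highest mean over all 15 arrays stood for the gene.

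The 15 arrays were grouped by the compound and exposure time of their labels into 5 groups of 3. Linear models were fitted to all 15 arrays with limma 3.58.1 in R 4.3.3, with 1 mean per group and 10 residual degrees of freedom. Contrasts were tested with limma's moderated test, two-sided, and p was adjusted by Benjamini and Hochberg over the 22746 probe sets. A probe set was called at an adjusted p under 0.05. The standard error (SE) beside a log2 fold change is the moderated one of the fit; group means stand beside the SD of 3 arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The comparisons, the tests, the first set of gene lists, the rule for named genes and most alternatives were chosen before the data were examined.

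Gene lists were tested with camera of limma at a preset correlation of 0.01 between genes, and again with an estimated correlation. A list needed 5 measured members, that is genes with a named probe set, each with 1 probe set. Other members may lie among the 8730 probe sets without a gene, so that list results describe the named members and not a whole family. There were 39 lists with 1181 symbols, of which 133 had a named probe set, and 7 of the 39 lists could be tested. A further 7 lists, written by locus tag and chosen after seeing how few symbols were named, could all be tested. Of the 84 tests, adjusted together, 39 were called at the preset correlation and 0 with an estimated correlation. The call of a list against the other genes therefore rests on the assumption of weakly correlated genes. Calls of single members, tested gene by gene, do not rest on it. Calls of members are given over all probe sets and adjusted over the list alone.

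Named genes were chosen by rule. For each contrast against the roots before treatment and each between the compounds, they were the 8 largest rises and the 8 largest falls among called genes whose groups of arrays did not overlap. For both contrasts over time they were the 4 largest each way among called genes, again with groups that did not overlap. The rule chosen beforehand did not ask for that limit over time. For the interaction they were the 4 largest each way among called genes. Added to these were fixed sentinel genes and up to 4 called members of each list, those with the largest change. If no member of a list was called, its 2 members with the smallest p were taken. Of the sentinels, only GH3.3, LBD16 and LBD29 had a named probe set. Chromosome positions are those of the RefSeq annotation of TAIR10.1. In a few places further genes were named after their values were seen, and the text says so there.

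The overlap of the responses to both compounds was set beside its value if calls were independent, and beside 100 simulated data sets without any effect but with the same shared arrays before treatment. Alternatives were a block for replicate number, only the arrays of a contrast, a trended and robust spread prior, array weights, another quantile normalization, median centring, leaving out dim probe sets (15025 remained), at least 2-fold, an adjusted p under 0.01, the mean of all probe sets of a gene, and leaving out each array. Scaling on the poly-A spike-in controls, leaving out replicate 3 of every group and a covariate for the main axis of variation within groups were chosen after seeing the data. So was a division of the 3 arrays before treatment, 1 to one compound and 2 to the other, in the overlap of the responses, and the count of called list members with 1 array left out. The fit was tested on simulated data with 200 of 22746 probe sets changed in the NAA 2 h contrast, over 5 simulated sets. It recovered 38.8% of changes of 0.50 log2, 90.4% of 1 and 99.1% of 2, with 4.8% false among the calls and a mean of 0.2 calls in a contrast without change. Its noise was independent between probe sets, whereas the real deviations within groups shared 1 axis with 45.1% of their variance. It therefore does not show the error rate of these arrays. The simulations without effect for the overlap, drawn from the real deviations, had a median of 0 shared calls but up to 927 at 2 h and 228 at 6 h.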

Results

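The arrays measured transcript levels in roots of Arabidopsis thaliana Col-0 seedlings in the lateral root inducible system. In this system seedlings germinate on NPA, an inhibitor of polar auxin transport that keeps lateral roots from starting, and are then moved to a compound that starts them. Seedlings grew on 10 µM NPA until 3 days after germination and were moved to 10 µM NAA, a synthetic auxin, or to 50 µM naxillin, a synthetic compound described in the labels as a non-auxin-like inducer of lateral roots. Roots were sampled before transfer and after 2 h and 6 h, which gave 5 groups: before treatment, NAA 2 h, NAA 6 h, naxillin 2 h and naxillin 6 h. Each group held 3 arrays from 3 independent experiments, and each sample was 500 root sections without meristems. No roots were moved to medium without a compound, so that a contrast with the roots before treatment holds the transfer and the elapsed time as well as the compound. The naxillin and NAA groups of the same time share transfer and time but differ in dose.

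Values on the 15 arrays ran from 2.99 to 14.83 on the log2 scale, and array medians lay between 7.08 and 7.18. Across probe sets, the correlation between replicates of a group was 0.984 to 0.9959, and the lowest between any 2 arrays was 0.8917; probe sets are not independent replicates. Values at the lower quartile of an array (4.69 to 4.8) were not shown to lie above background. Changes from levels near it, as for GH3.1, PUCHI, AT4G12580 and AT3G57950, are differences of RMA values and not measured folds. Near the highest values of the arrays (14.58 to 14.83) a further rise may not register. The first principal component held 70.4% of the variance, the second 10.7% and the third 5.4%. The number of arrays limits the precision of every value below: n = 3 per group throughout.

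Genes of the auxin response and of lateral root initiation rose steeply with NAA within 2 h. GH3.1 (AT2G14960), which belongs to a family of enzymes that join amino acids to auxin, went from 4.77 ± 0.30 (SD, n = 3) before treatment to 11.09 ± 0.33, a rise of 6.32 log2 units (SE 0.18, adjusted p = 3.74e-11). LBD29 (AT3G58190) and LBD16 (AT2G42430), transcription factors that act in lateral root initiation, rose 41.8-fold (log2 5.38, SE 0.20) and 12.6-fold (log2 3.65, SE 0.13). PUCHI (AT5G18560), a transcription factor of the early lateral root primordium, rose by 3.24 (SE 0.18). GH3.3 (AT2G23170) was already at 10.52 ± 0.59 before treatment and rose by 3.99 log2 units (SE 0.34) to 14.50 ± 0.04. That is close to the highest values of the arrays; whether the probe set was at its ceiling was not tested. In TAIR10.1 coordinates, LBD16 lies on chromosome 2 from 17663353 to 17665337, LBD29 on chromosome 3 from 21548484 to 21549572 and GH3.3 on chromosome 2 from 9863855 to 9866562.

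**Figure D1:**
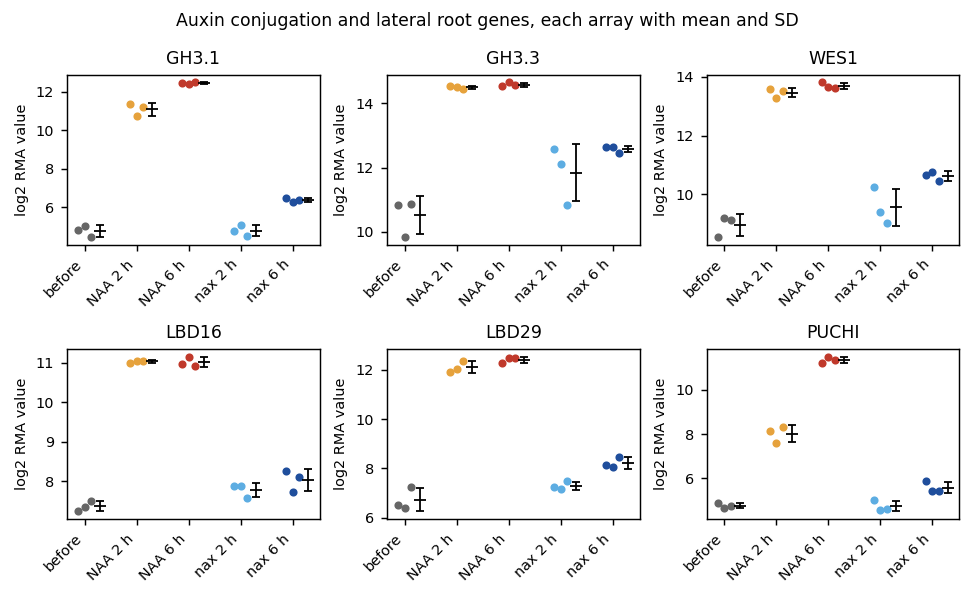
Log2 expression of auxin response and lateral root genes on each of the 15 arrays, by group, with points for arrays and bars for the group mean and SD (n = 3). LBD16 went from 7.37 before treatment to 11.02 with NAA at 2 h, and reached 7.78 and 8.03 with naxillin at 2 h and 6 h.

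Of the 5 GH3 enzymes measured, 3 rose with NAA at 2 h and 1, GH3.17, fell by 1.46 log2 units, with the same counts adjusted over the list alone (median 3.99, camera adjusted p = 0.00188, adjusted p = 0.186 with an estimated correlation). WES1 (AT4G27260), the gene of GH3.5, rose by 4.51 (SE 0.25). Among the Aux/IAA repressors, which auxin induces and which in turn hold back its response, 4 of 7 measured rose and 0 fell, also adjusted over the list alone (median 0.69, camera adjusted p = 1.49e-05, adjusted p = 0.186 with an estimated correlation). IAA29 rose by 4.96 (SE 0.15) and IAA30 by 4.16 (SE 0.16). The lateral root regulators LBD16, LBD29 and PUCHI, 3 measured, all rose. Genes for ribosome assembly rose as well: 31 of 33 assembly factors were called higher and 0 lower, the same adjusted over the list alone (median 1.1, camera adjusted p = 1.05e-18, adjusted p = 0.215 with an estimated correlation). AT3G12860 rose by 2.48 and AT5G08180 by 1.62. Of 102 cytosolic ribosomal proteins 29 rose and 0 fell, or 32 and 0 adjusted over the list alone (median 0.37, camera adjusted p = 6.92e-13, adjusted p = 0.549 with an estimated correlation). With 1 array left out, 13 to 28 of them rose, and 26 to 31 of the assembly factors.

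Genes tied to stress and detoxification also moved with NAA at 2 h. Of 8 genes of wounding, touch and handling, 6 rose, or 7 adjusted over the list alone, and 0 fell (median 0.99, camera adjusted p = 7.55e-08, adjusted p = 0.179 with an estimated correlation), with WRKY53 at 2.81 (SE 0.14). Of 17 xenobiotic detoxification genes 8 rose and 1 fell, or 8 and 2 adjusted over the list alone (median 0.38, camera adjusted p = 0.000242, adjusted p = 0.215 with an estimated correlation). GSTU25, a glutathione S-transferase, rose by 2.62 (SE 0.23, adjusted p = 2.04e-06) and the glycosyltransferase gene UGT73B4 by 2.11 (SE 0.16). All 6 measured shoot and photosynthesis genes fell, also adjusted over the list alone (median −0.75, camera adjusted p = 0.000828, adjusted p = 0.258 with an estimated correlation), LHCB4.2 by −2.29. With 1 array left out, 4 to 6 of them fell. Cell wall loosening genes went both ways, 6 higher and 4 lower of 27, or 8 and 4 adjusted over the list alone (median 0.06, camera adjusted p = 0.081); XTH18, a xyloglucan endotransglucosylase/hydrolase, rose by 2.99. Of 55 class III peroxidases 7 rose and 3 fell (median 0.03, camera adjusted p = 0.165). Of 53 pectin-modifying enzymes 8 rose and 7 fell (camera adjusted p = 0.846), with a median of −0.04, a mean of 0.05 and a median of 0.06 under poly-A spike-in scaling. Leaving out 1 array, 7 to 9 of these enzymes rose and 4 to 7 fell, and 5 to 8 of the peroxidases rose and 1 to 3 fell. Genes of division had not moved as groups at 2 h: 0 of 8 DNA replication genes (median 0.11) and 0 of 24 mitosis genes (median −0.09, but 0.01 under poly-A spike-in scaling) were called.

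Among the other genes with the largest changes, AT4G37290 rose by 6.12 (SE 0.19) and AT4G37295 by 4.73 (SE 0.13), while AT2G28780 fell by 3.69 (SE 0.28) and OCT1, a transporter gene of the organic cation family, fell by 3.28 (SE 0.36). AT1G19530 fell by 3.31 (adjusted p = 0.0175), but without NAA_2h replicate 3 its adjusted p was 0.0793 and without NPA_0h replicate 2 it was 0.0722. Across the 22746 probe sets, limma called 5858 for NAA at 2 h against before treatment, 2389 higher and 3469 lower; at least 2-fold were 812 and 610. The groups of arrays did not overlap at 8604 probe sets (37.8%, where chance gives 10%). Here and below, the 10% is an expectation per probe set. Its spread over correlated probe sets was not measured. The excess of falls turned with scaling on the poly-A spike-in controls, which called 2975 higher and 2277 lower.

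At 6 h of NAA the early auxin genes were still high, and genes of DNA replication and mitosis were called higher as well. GH3.1 stood 7.68 log2 units above the level before treatment (SE 0.18, adjusted p = 9.71e-13), LBD29 at 5.69 (SE 0.20) and LBD16 at 3.64 (SE 0.13). PUCHI reached 11.34 ± 0.15 (SD, n = 3) from 4.77 ± 0.11, a difference of 6.57 (SE 0.18). All 8 measured DNA replication genes rose, also adjusted over the list alone (median 1.52, camera adjusted p = 2.93e-05, adjusted p = 0.215 with an estimated correlation), among them PRL, the gene of the replicative helicase subunit MCM7, by 2.56 (SE 0.24). Of 24 mitosis genes 22 rose and 0 fell, or 23 and 1 adjusted over the list alone (median 1.51, camera adjusted p = 2.89e-08, adjusted p = 0.366 with an estimated correlation), including the Aurora kinase gene AUR3 by 2.21 (SE 0.16).

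All 33 ribosome assembly factors rose at 6 h of NAA (median 2.63, camera adjusted p = 1.91e-19, adjusted p = 0.215 with an estimated correlation). So did 101 of 102 cytosolic ribosomal proteins (median 1.47, camera adjusted p = 5.76e-30, adjusted p = 0.268 with an estimated correlation). Counts adjusted over the list alone were the same. The list of G2/M and cytokinesis, written by symbols, shares AUR3 with the mitosis list, so that its result is not separate evidence. Of its 5 genes 4 rose and 0 fell, or 4 and 1 adjusted over the list alone (median 1.43, camera adjusted p = 0.0244, adjusted p = 0.459 with an estimated correlation). Without dim probe sets its adjusted p was 0.0605. Core histones gave 6 higher and 1 lower of 8 (median 0.47, camera adjusted p = 0.149). Of the auxin lists, 4 of 7 Aux/IAA repressors rose (median 1.84, camera adjusted p = 0.00216, adjusted p = 0.215 with an estimated correlation). So did 3 of 5 GH3 enzymes (median 4.07, camera adjusted p = 0.00293, adjusted p = 0.186 with an estimated correlation). Neither list had a fall, and counts were the same adjusted over the list alone.

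NAA at 6 h also lowered genes steeply. AT4G30450 went from 12.68 ± 0.14 to 6.12 ± 0.05 (SD, n = 3), a fall of 94.3-fold (log2 −6.56, SE 0.20, adjusted p = 1.85e-11), and AT3G53980 fell by 6.01 log2 units from 13.96 ± 0.04. The subtilase gene ATSBT5.2 fell by 5.87 (SE 0.21). All 6 shoot and photosynthesis genes fell, also adjusted over the list alone (median −2.07, camera adjusted p = 0.000124, adjusted p = 0.215 with an estimated correlation). Wall and detoxification lists split. The pectate lyase genes AT1G67750 and AT1G04680 rose by 6.28 (SE 0.25) and 5.61, in a list of 53 pectin-modifying enzymes with 13 higher and 13 lower (median 0.08, camera adjusted p = 0.592). Among xenobiotic detoxification genes 5 rose and 5 fell of 17, GSTU26 by −3.24 (SE 0.26), with a list median of −0.17 (camera adjusted p = 0.855) that became 0.11 under poly-A spike-in scaling. Of 55 class III peroxidases 10 rose and 19 fell (median −0.05, camera adjusted p = 0.446), with a median of 0.01 under median centring and 0.23 under poly-A spike-in scaling. Cell wall loosening genes were 8 higher and 7 lower of 27 (camera adjusted p = 0.895), with a median of −0.14, a mean of 0.01 and a median of 0.14 under poly-A spike-in scaling. Wounding, touch and handling genes were 2 higher and 2 lower of 8 (median −0.11, or 0.17 under poly-A spike-in scaling; camera adjusted p = 0.868).

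In this contrast limma called 11858 probe sets, 52.1% of those tested, 5181 higher and 6677 lower; at least 2-fold were 2320 and 2234. The groups did not overlap at 13597 probe sets (59.8%, where chance gives 10%). Which direction was more frequent depended on the scaling: poly-A spike-in scaling moved the median of all probe sets from −0.03 to 0.25 and gave 10950 higher and 4265 lower. Changes at 6 h of NAA are therefore relative to the median of the array.

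**Figure D2:**
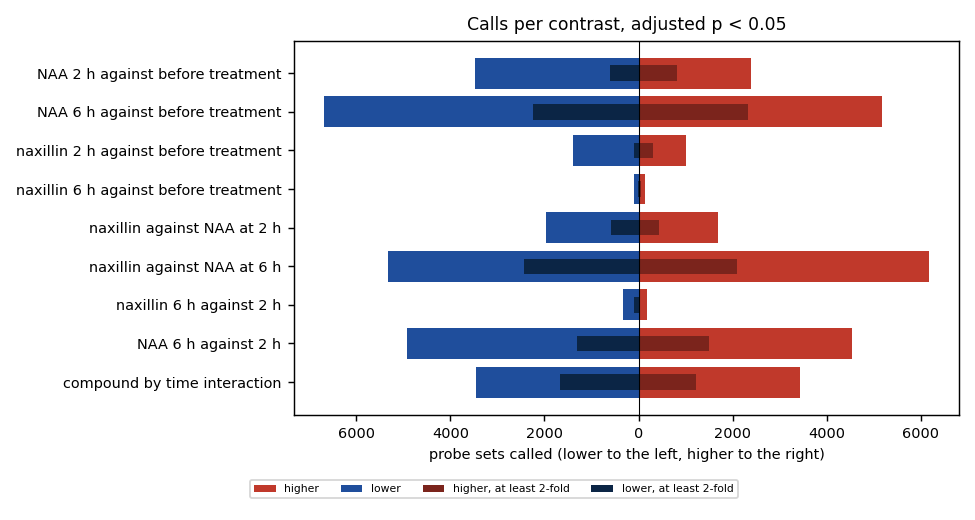
Number of probe sets called higher (right) and lower (left) in each contrast, out of 22746, with the calls of at least 2-fold as dark bars. NAA called 5858 at 2 h and 11858 at 6 h and naxillin 2402 and 219; which direction held more calls turned under poly-A spike-in scaling for NAA and naxillin at both times, for naxillin against NAA at 6 h and for NAA 6 h against 2 h.

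With naxillin at 2 h, genes of detoxification and of cell wall loosening were higher than before treatment, while the genes of lateral root initiation had small changes. Some of the former, GSTU25 and XTH18 among them, also rose with NAA, and neither list was called different between the compounds at 2 h. Their rise cannot be told apart from transfer and elapsed time. MSRB9 (AT4G21850), a methionine sulfoxide reductase, rose 6.76-fold (log2 2.76, SE 0.40, adjusted p = 0.00118), from 7.69 ± 0.41 to 10.44 ± 0.81 (SD, n = 3). AT4G12580 rose by 2.82 (SE 0.22, adjusted p = 4.19e-05) and the late embryogenesis abundant gene LEA4-5 by 2.45 (SE 0.49). GSTU25 rose by 2.04 (SE 0.23, adjusted p = 0.000188), XTH18 by 2.14 (SE 0.30) and the expansin genes EXPA7 and EXPA18, both known from root hairs, by 1.57 (SE 0.29) and 1.44 (SE 0.30). GH3.3 was called at 1.33 (SE 0.34, adjusted p = 0.0265). It was not called without naxillin_2h replicate 1 (0.96, adjusted p = 0.0797), without naxillin_2h replicate 2 (1.2, adjusted p = 0.1) or without NPA_0h replicate 2 (0.99, adjusted p = 0.113). LBD29 stood at 0.56 (SE 0.20, adjusted p = 0.0933) and LBD16 at 0.41 (SE 0.13, adjusted p = 0.0647), neither called over all probe sets. Of the 3 lateral root regulators 0 were called, or 2 adjusted over the list alone.

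**Figure D3:**
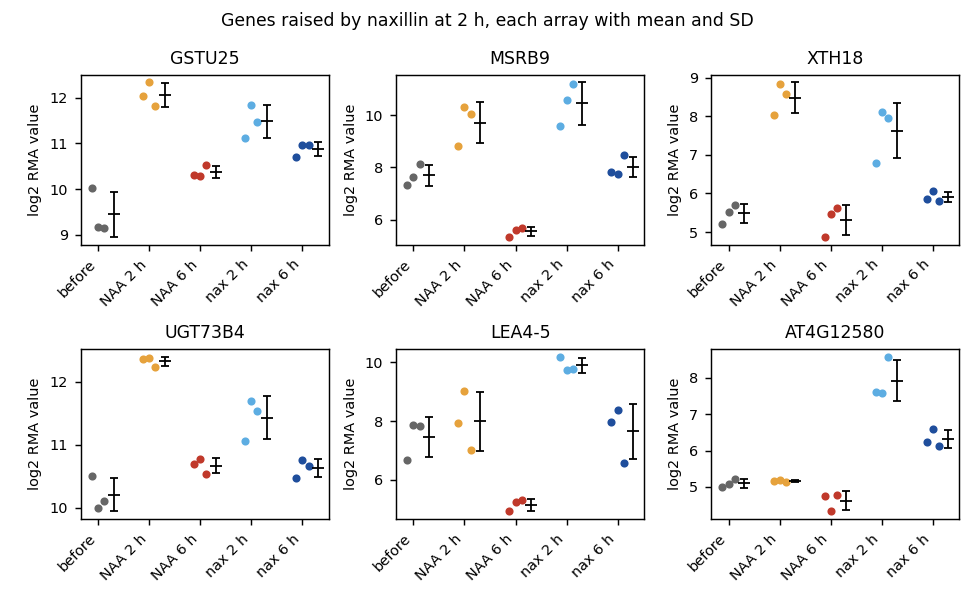
Log2 expression of 6 genes higher with naxillin at 2 h than before treatment, on each array, with the group mean and SD (n = 3). MSRB9 went from 7.69 before treatment to 10.44 with naxillin at 2 h and 8.01 at 6 h, and AT4G12580 from 5.10 to 7.92 and 6.31, against 5.17 with NAA at 2 h. MSRB9, GSTU25, XTH18 and UGT73B4 rose with NAA at 2 h as well, MSRB9 to 8.81, 10.29 and 10.03 on the arrays. LEA4-5 and AT4G12580 were higher with naxillin than with NAA at 2 h.

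By list, 10 of 17 xenobiotic detoxification genes rose with naxillin at 2 h, or 11 adjusted over the list alone, and 0 fell (median 0.50, camera adjusted p = 8.32e-08, adjusted p = 0.179 with an estimated correlation). Leaving out 1 array, 3 to 7 of them rose. Of 27 cell wall loosening genes 6 rose, or 7 adjusted over the list alone, and 0 fell (median 0.24, camera adjusted p = 3.25e-06, adjusted p = 0.179 with an estimated correlation). XTH21 rose by 1.63 (SE 0.15). Of 53 pectin-modifying enzymes, another list of the cell wall, 3 rose and 2 fell. Of 55 class III peroxidases 7 rose and 1 fell, or 7 and 2 adjusted over the list alone (median 0.14, camera adjusted p = 0.000242, adjusted p = 0.186 with an estimated correlation), AT4G26010 by 1.56. Leaving out 1 array, 1 to 6 rose and 0 or 1 fell. The adjusted p of AT4G26010 was 0.0539 and 0.112 without naxillin_2h replicate 1 and 2, and 0.094 and 0.0863 without NPA_0h replicate 2 and 3. AT1G30870 (0.139 and 0.108), AT1G44970 (0.0772 and 0.0733) and Prx37 (0.124 and 0.143) also lost their calls without naxillin_2h replicate 2 or NPA_0h replicate 2. Of the 8 wounding, touch and handling genes 4 rose and 0 fell (median 0.33, camera adjusted p = 0.0021, adjusted p = 0.215 with an estimated correlation), among them WRKY22 by 1.4 (SE 0.17, adjusted p = 0.000401). Leaving out 1 array, 1 or 2 of them were called. Without NPA_0h replicate 1 the adjusted p was 0.0834 for CML37, 0.0632 for CML38 and 0.143 for WRKY6, and without naxillin_2h replicate 3 it was 0.0894, 0.105 and 0.149. Of 6 shoot and photosynthesis genes 2 fell, or 3 adjusted over the list alone (median −0.47, camera adjusted p = 0.00471, adjusted p = 0.352 with an estimated correlation). Both fell weakly, LHCB4.2 by −1.22 (adjusted p = 0.0462) and RCA by −0.55 (adjusted p = 0.0474). LHCB4.2 was no longer called without naxillin_2h replicate 2 (adjusted p = 0.125) or 3 (0.175), without NPA_0h replicate 1 (0.101), 2 (0.163) or 3 (0.0645), or under poly-A spike-in scaling (0.0566). In the same cases RCA had an adjusted p of 0.0946, 0.188, 0.0938, 0.176, 0.0631 and 0.0851. Of 5 GH3 enzymes 1 rose, or 2 with 1 lower adjusted over the list alone (median 0.03, camera adjusted p = 0.378). Of 7 Aux/IAA repressors 1 rose, IAA18 by 0.31 (adjusted p = 0.048). Its adjusted p was 0.0704, 0.127 and 0.133 without naxillin_2h replicate 1, 2 and 3, and 0.131 and 0.144 without NPA_0h replicate 1 and 3. The median of the repressors was 0.08 (camera adjusted p = 0.369). Growth lists had few calls. None of 33 assembly factors (median 0.12, camera adjusted p = 0.11), 8 DNA replication genes or 24 mitosis genes was called, and of 102 ribosomal proteins 1 was lower (median −0.05, or 0.03 under poly-A spike-in scaling; camera adjusted p = 0.895).

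Among the falls with naxillin at 2 h, AT2G28780 dropped by 1.99 (SE 0.28, adjusted p = 0.000925) and TRI by 1.75 (SE 0.21). Across all probe sets limma called 2402, 1001 higher and 1401 lower; at least 2-fold were 302 and 86. Groups did not overlap at 6427 probe sets (28.3%, where chance gives 10%). The larger share of falls depended on the scaling: poly-A spike-in scaling called 1208 higher and 684 lower, and median centring 1154 and 797. Single arrays mattered too: 1188 probe sets were called without naxillin_2h replicate 2, 1176 without naxillin_2h replicate 3, 1131 without NPA_0h replicate 2 and 1262 without NPA_0h replicate 3.

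At 6 h of naxillin fewer probe sets were called, and several auxin response genes were among the largest rises. GH3.3 was 4.17-fold above the level before treatment (log2 2.06, SE 0.34, adjusted p = 0.013), WES1 3.18-fold (log2 1.67, SE 0.25, adjusted p = 0.00813) and LBD29 2.82-fold (log2 1.5, SE 0.20, adjusted p = 0.00615). GH3.1 rose by 1.61 (SE 0.18, adjusted p = 0.00396). LBD16 rose 1.58-fold (log2 0.66, SE 0.13, adjusted p = 0.0332). AT5G17340 rose by 1.79 (SE 0.24) and AT3G24240 by 1.75 (SE 0.23), whereas AT3G12900 fell by 2.65 (SE 0.45) and AT4G10510 by 1.41 (SE 0.17). LBD16 lost its call without naxillin_6h replicate 1 (0.54, adjusted p = 0.12) or naxillin_6h replicate 3 (0.61, adjusted p = 0.101). It also did so without NPA_0h replicate 1 (0.60, adjusted p = 0.0874), NPA_0h replicate 2 (0.64, adjusted p = 0.121) or NPA_0h replicate 3 (0.73, adjusted p = 0.0633), and under poly-A spike-in scaling (0.59, adjusted p = 0.0627). GH3.3 lost its call without naxillin_6h replicate 1 (2.03, adjusted p = 0.0537) or NPA_0h replicate 2 (1.72, adjusted p = 0.0648). AT3G12900 did so without NPA_0h replicate 2 (−2.80, adjusted p = 0.0513) or 3 (−2.48, adjusted p = 0.0722). Without replicate 3 of every group the adjusted p was 0.0634 for AT5G17340, 0.168 for AT3G12900 and 0.178 for LBD16.

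Of 5 GH3 enzymes 3 rose with naxillin at 6 h and 0 fell, or 3 and 1 adjusted over the list alone (median 1.61, camera adjusted p = 0.000299, adjusted p = 0.179 with an estimated correlation). Of the 3 lateral root regulators 2 rose, or 3 adjusted over the list alone. Of 29 Aux/IAA repressors listed, 7 had a named probe set and 0 of these were called (median 0.01, or −0.06 under poly-A spike-in scaling, camera adjusted p = 0.793). The early lists had fewer called members, as fewer probe sets were called in all. No list was tested between 2 h and 6 h. Of 17 xenobiotic detoxification genes 1 rose, GSTU25 by 1.43 (SE 0.23). The list median was 0.26 (camera adjusted p = 3.07e-05, adjusted p = 0.186 with an estimated correlation). GSTU25 itself was not called without NPA_0h replicate 2 (1.3, adjusted p = 0.059) or NPA_0h replicate 3 (1.29, adjusted p = 0.0562), nor without replicate 3 of every group (adjusted p = 0.176). Class III peroxidases were 2 higher and 1 lower of 55, or 7 and 4 adjusted over the list alone (median 0.05, but −0.02 under poly-A spike-in scaling; camera adjusted p = 0.0131, adjusted p = 0.265 with an estimated correlation). The list's adjusted p was 0.102 without naxillin_6h replicate 1. Its 3 called members lost their calls without NPA_0h replicate 2 (AT4G36430 0.174, Prx37 0.0924, AT2G18980 0.082) or NPA_0h replicate 3 (0.103, 0.0757 and 0.157). With 1 array left out, 0 to 5 were higher. Of 8 wounding, touch and handling genes 1 rose, WRKY22 by 0.94, with an adjusted p of 0.0707 and 0.0634 without naxillin_6h replicate 2 and 3, and 0.0846 and 0.0812 without NPA_0h replicate 2 and 3. The list median was 0.11 (camera adjusted p = 0.0479, adjusted p = 0.445 with an estimated correlation), and it was not called without naxillin_6h replicate 2 (adjusted p = 0.242), NPA_0h replicate 1 (adjusted p = 0.199) or NPA_0h replicate 3 (adjusted p = 0.165).

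Among lists without a called member at 6 h of naxillin were the 6 shoot and photosynthesis genes (median −0.37, camera adjusted p = 0.0046, adjusted p = 0.352 with an estimated correlation). Their adjusted p was 0.0773 without naxillin_6h replicate 3 and 0.057 without NPA_0h replicate 2. The 102 ribosomal proteins had 0 calls and a median of −0.21 (camera adjusted p = 2.65e-05, adjusted p = 0.755 with an estimated correlation). Their adjusted p was 0.433 without naxillin_6h replicate 2 and 0.104 without NPA_0h replicate 3. Within groups, their mean followed the main axis of variation between replicates (r = 0.97 over 15 arrays), as did that of the assembly factors (r = 0.97) and, in the other direction, of the shoot and photosynthesis genes (r = −0.88). On this axis naxillin_6h replicate 3 lay farthest out. The 33 assembly factors (median −0.13, camera adjusted p = 0.693), the 8 DNA replication genes, the 24 mitosis genes (median −0.06) and the 27 cell wall loosening genes (median −0.01, or 0.05 under median centring; camera adjusted p = 0.824) had 0 calls as well.

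In this contrast limma called 219 probe sets, 132 higher and 87 lower, with 62 and 18 at least 2-fold; 3044 had an unadjusted p under 0.05. Groups did not overlap at 4155 probe sets (18.3%, where chance gives 10%). As the spread of that 10% over correlated probe sets was not measured, the share does not show an excess. Poly-A spike-in scaling turned the balance to 107 higher and 282 lower. The poly-A controls stood at 0.07 against before treatment but the hybridization controls, added after labelling, at −0.12, so that the kinds of control moved in opposite directions. Array weights raised the count to 2694. The count was 90 without naxillin_6h replicate 1, 106 without naxillin_6h replicate 2, 133 without naxillin_6h replicate 3, 50 without NPA_0h replicate 2 and 63 without NPA_0h replicate 3.

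Set against each other at 2 h, the compounds differed in genes of the auxin response and lateral root initiation. With naxillin GH3.1 stood 6.30 log2 units below NAA (log2 −6.30, SE 0.18, adjusted p = 4.79e-11), LBD29 at −4.82 (SE 0.20), WES1 at −3.91, PUCHI at −3.26, LBD16 at −3.25 (SE 0.13) and GH3.3 at −2.65 (SE 0.34, adjusted p = 0.000111). All 3 lateral root regulators were lower. So were 4 of 7 Aux/IAA repressors, with 0 higher (median −0.65, camera adjusted p = 2.43e-06, adjusted p = 0.179 with an estimated correlation). Lower too were 28 of 33 assembly factors, or 32 adjusted over the list alone (median −1.02, camera adjusted p = 8.82e-19, adjusted p = 0.215 with an estimated correlation). Of 102 ribosomal proteins 23 were lower, or 48 adjusted over the list alone (median −0.43, camera adjusted p = 1.42e-17, adjusted p = 0.445 with an estimated correlation). Leaving out 1 array, 8 to 40 of these and 17 to 29 of the assembly factors were lower. Of 5 GH3 enzymes 3 were lower and 1 higher (median −2.65, camera adjusted p = 0.00152, adjusted p = 0.186 with an estimated correlation). Of 8 wounding, touch and handling genes 4 were lower and 0 higher, or 5 and 1 adjusted over the list alone (median −0.82, camera adjusted p = 0.000228, adjusted p = 0.211 with an estimated correlation).

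Genes higher with naxillin than with NAA at 2 h included AT2G34610 by 3.69 (SE 0.29), OCT1 by 3.49 (SE 0.36), AT4G12580 by 2.75 (95% interval 2.28 to 3.23), XTH21 by 2.5 (2.17 to 2.83) and LEA4-5 by 1.90 (0.84 to 2.97, adjusted p = 0.0164). OCT1 had fallen with NAA at 2 h, with arrays at 5.14 to 6.37. They were at 8.44 to 9.5 before treatment and at 8.49 to 9.69 with naxillin at 2 h. Several genes that naxillin raised at 2 h were not called different. MSRB9 stood at 0.73 (95% interval −0.13 to 1.60, adjusted p = 0.272), GSTU25 at −0.59 (−1.07 to −0.10, adjusted p = 0.103) and XTH18 at −0.85 (−1.50 to −0.20, adjusted p = 0.0753). WRKY22 stood at −0.14 (−0.51 to 0.24, adjusted p = 0.701) and CML38 at −0.08 (−0.62 to 0.46, adjusted p = 0.895). These intervals are of single genes and were not widened for the number of genes. The xenobiotic list had 3 higher and 4 lower, or 3 and 6 adjusted over the list alone (median −0.20, camera adjusted p = 0.324). Cell wall loosening genes were 5 higher and 3 lower (median 0.17, camera adjusted p = 0.243) and class III peroxidases 4 higher and 5 lower (median 0.12, camera adjusted p = 0.254). Leaving out 1 array, 3 to 5 of the peroxidases were higher and 1 to 4 lower. Pectin-modifying enzymes were 8 and 6 (median 0.04, camera adjusted p = 0.693) and shoot and photosynthesis genes 1 higher and 0 lower (median 0.27, camera adjusted p = 0.081). In all, limma called 3657 probe sets, 1682 higher with naxillin and 1975 lower, and 1020 at least 2-fold.

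At 6 h the compounds differed in genes of ribosome production, DNA replication and mitosis. Lower with naxillin than with NAA were all 33 assembly factors (median −2.72, camera adjusted p = 1.45e-19, adjusted p = 0.215 with an estimated correlation). So were 100 of 102 ribosomal proteins, or 101 adjusted over the list alone (median −1.69, camera adjusted p = 1.92e-32, adjusted p = 0.258 with an estimated correlation). Also lower were all 8 DNA replication genes (median −1.60, camera adjusted p = 2.93e-05, adjusted p = 0.215 with an estimated correlation) and 23 of 24 mitosis genes (median −1.59, camera adjusted p = 1.1e-08, adjusted p = 0.352 with an estimated correlation). All 6 shoot and photosynthesis genes were higher (median 1.71, camera adjusted p = 0.000252, adjusted p = 0.215 with an estimated correlation). The pectate lyase gene AT1G67750 was lower by 6.49 (log2 −6.49, SE 0.25), GH3.1 by 6.08 (log2 −6.08, SE 0.18). PUCHI stood at −5.76 (SE 0.18), LBD29 at −4.20, LBD16 at −2.99 and GH3.3 at −2.01 (SE 0.34, adjusted p = 0.000179). AT4G30450, which NAA lowered, was higher by 6.10 (SE 0.20) and AT3G53980 by 5.99 (SE 0.17).

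Of the other lists at 6 h, 4 of 7 Aux/IAA repressors were lower (median −1.82, camera adjusted p = 0.00237, adjusted p = 0.215 with an estimated correlation). The same held for 4 of 5 GH3 enzymes, or 5 adjusted over the list alone (median −2.01, camera adjusted p = 0.00293, adjusted p = 0.186 with an estimated correlation), and 4 of 5 genes of G2/M and cytokinesis (median −1.53, camera adjusted p = 0.0204, adjusted p = 0.445 with an estimated correlation). Without dim probe sets the adjusted p of the last list was 0.0609, and this list shares AUR3 with the mitosis list. Core histones were 1 higher and 4 lower (median −0.47, camera adjusted p = 0.124). Lists without a called difference at 6 h held members of both directions. Xenobiotic detoxification had 7 higher and 3 lower (median 0.32, or −0.02 under poly-A spike-in scaling; camera adjusted p = 0.18). Class III peroxidases had 18 and 8 (median 0.11, or −0.24 under that scaling, camera adjusted p = 0.109). Cell wall loosening had 6 and 7 (median 0.08, or −0.27 under that scaling, mean −0.07, camera adjusted p = 0.927). Wounding, touch and handling had 2 and 2 (median 0.12, or −0.23 under that scaling). In all, limma called 11511 probe sets, 6177 higher with naxillin and 5334 lower. Poly-A spike-in scaling turned this balance to 3404 and 12888, and the median of all probe sets moved from 0.02 to −0.33.

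**Figure D4:**
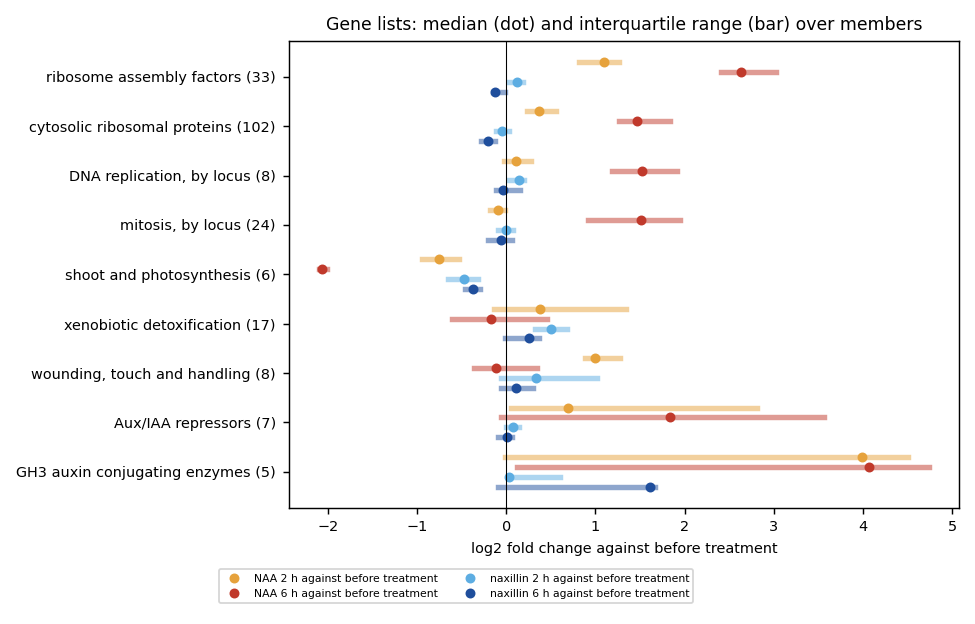
Median (dot) and interquartile range (bar) of the log2 fold change over the members of 9 gene lists, in the 4 contrasts against the roots before treatment, with the number of members beside each list. Ribosome assembly factors stood at 1.1 and 2.63 with NAA at 2 h and 6 h against 0.12 and −0.13 with naxillin, while medians near 0 changed sign under poly-A spike-in scaling for xenobiotic detoxification (−0.17 to 0.11) and wounding, touch and handling (−0.11 to 0.17) with NAA at 6 h, mitosis with NAA at 2 h (−0.09 to 0.01), ribosomal proteins with naxillin at 2 h (−0.05 to 0.03) and Aux/IAA repressors with naxillin at 6 h (0.01 to −0.06), and under median centring for DNA replication with naxillin at 6 h (−0.04 to 0.02).

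Between 2 h and 6 h of naxillin, early genes came down while some auxin genes went up. MSRB9 fell by 2.43 log2 units (SE 0.40, adjusted p = 0.00845), AT5G19110 by 2.13 (SE 0.32), XTH21 by 1.98 (SE 0.15, adjusted p = 0.000111) and LEA4-5 by 2.25 (SE 0.49, adjusted p = 0.0305). GH3.1 rose by 1.59 (SE 0.18, adjusted p = 0.00119) and AT5G17340 by 1.97 (SE 0.24, adjusted p = 0.00182). LBD29 rose by 0.93 (adjusted p = 0.0277). Its adjusted p was 0.0613 without naxillin_2h replicate 1, 0.111 without naxillin_2h replicate 2, 0.0526 without naxillin_2h replicate 3, 0.0709 without naxillin_6h replicate 1 and 0.0804 without naxillin_6h replicate 3. LEA4-5 had an adjusted p of 0.0715, 0.0828, 0.0889, 0.0714 and 0.0794 in the same cases. Without replicate 3 of every group it was 0.135 for LEA4-5, 0.0826 for MSRB9 and 0.0592 for AT5G19110. GH3.3 (0.73, adjusted p = 0.354) and LBD16 (0.25, adjusted p = 0.417) were not called. In all, limma called 520 probe sets, 185 higher and 335 lower at 6 h, but 222 without naxillin_2h replicate 2, 198 without naxillin_2h replicate 3 and 221 without naxillin_6h replicate 1. Poly-A spike-in scaling gave 76 higher and 1094 lower.

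Between 2 h and 6 h of NAA many probe sets changed, while LBD16 (−0.01, but 0.17 under poly-A spike-in scaling, adjusted p = 0.955) and LBD29 (0.31, adjusted p = 0.257) were not called. Not all early genes stood still. PUCHI arrays lay at 7.58 to 8.32 at 2 h and at 11.19 to 11.48 at 6 h. The 175 probe sets raised at least 4-fold by NAA at 2 h had medians of 2.57 and 3.14 against before treatment. GH3.3 (0.09, adjusted p = 0.876) was close to the highest values of the arrays at both times, where a further rise may not register. AT3G57950 went from 3.88 ± 0.13 to 9.24 ± 0.23 (SD, n = 3), a rise of 5.36 (SE 0.12, adjusted p = 3.52e-12), and PR-1-LIKE rose by 5.07 (SE 0.13). BCAT4, an aminotransferase of methionine-derived glucosinolate synthesis, fell by 4.81 (SE 0.53), and AT3G53980 by 5.82 (SE 0.17). In all, limma called 9454 probe sets, 4537 higher and 4917 lower, which poly-A spike-in scaling turned to 7884 and 3121.

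The interaction asked whether the difference between the compounds changed from 2 h to 6 h. It did so most for AT3G53980 (5.83, SE 0.24, adjusted p = 2.63e-09), which was at 13.94 ± 0.09 and 13.95 ± 0.01 (SD, n = 3) with naxillin at 2 h and 6 h but went from 13.77 ± 0.07 to 7.95 ± 0.50 with NAA. AT3G57950 had the opposite sign (−5.21, SE 0.17). For LBD29 (0.63, adjusted p = 0.117) and LBD16 (0.26, or −0.06 under poly-A spike-in scaling, adjusted p = 0.332) a change of the gap was not called. The value of GH3.3 (0.64, adjusted p = 0.375) has the limit given for its change over time. In all, limma called 6898 probe sets, 3437 with a positive and 3461 with a negative interaction, or 1555 and 8673 under poly-A spike-in scaling.

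Many of the genes that naxillin changed moved the same way with NAA. At 2 h, 468 probe sets were called higher with both compounds and 944 lower with both, where independent calls would give 105.1 and 213.7; 64 went in opposite directions. Of the probe sets that naxillin raised, 46.8% were also raised by NAA, and 67.4% of those it lowered were also lowered. Both contrasts use the same arrays before treatment, which alone creates likeness: the correlation of log2 fold changes across probe sets was 0.5, and simulations without any effect gave a median of 0.52 (−0.56 to 0.93). The covariance was 0.091 against a simulated mean of 0.014. The simulated count in the same direction had a median of 0 and a highest value of 927 over 100 draws, against 1412 observed. At either time such simulations hold no effect of either compound, so that they cannot decide how alike the responses are. In a test chosen after these values were seen, the 3 arrays before treatment were divided in each of 6 ways, 1 to one compound and the others to the other. The divisions gave 135 to 494 probe sets in the same direction, where independent calls would give 25.6 to 101.3, and a correlation of 0.36 to 0.45. In each division 1 contrast has a single array before treatment, for which the other groups supply the spread, and the count depended on which array it was. How much of the likeness comes from sharing these arrays is left open, and both compounds also share the transfer and the elapsed time. The count was 719 without naxillin_2h replicate 2, 651 without naxillin_2h replicate 3, 598 without NPA_0h replicate 2 and 750 without NPA_0h replicate 3.

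At 6 h the overlap was 59 probe sets higher with both and 63 lower with both, against 30.1 and 25.5 for independent calls, and 51 went in opposite directions. The correlation across probe sets was 0.17 against a simulated median of 0.54 (−0.36 to 0.93), the covariance 0.04 against 0.017, and the 122 in the same direction lay below the highest simulated count of 228, with 1 of 100 draws as high. The divided arrays gave 1 to 94 in the same direction, against 0.2 to 46.8 for independent calls, and a correlation of 0.05 to 0.18. The count was 61 without naxillin_6h replicate 1, 70 without naxillin_6h replicate 2, 73 without naxillin_6h replicate 3, 35 without NPA_0h replicate 2 and 45 without NPA_0h replicate 3.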

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

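The tests of handling at 2 h, of both explanations for the falls with NAA at 6 h, of replicate number, low sugar and the ribosome lists on the shared axis, and with array weights were chosen only after the result was seen. The handling test was divided into 2 parts and left without a bound against handling, and the rule for more mRNA was tightened, after their values were known.

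A difference between groups stood out in the compound by time interaction, where 6898 probe sets were called. AT3G53980 (5.83), AT4G30450 (4.92), AT4G11190 (4.43) and AT3G62040 (4.38) fell with NAA between 2 h and 6 h, with no comparable fall with naxillin. AT3G57950 (−5.21), PR-1-LIKE (−5.18), AT1G05577 (−5.16) and AT2G19970 (−5.16) rose late with NAA. Outside the main measurement, 24 of 45 spike-in controls were called lower with NAA at 6 h than before treatment.

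Naxillin called 2402 probe sets at 2 h and 219 at 6 h, though with array weights the counts were 3497 and 2694; the early genes MSRB9, LEA4-5 and XTH21 came back down. Transfer and handling cannot be told apart from the compound, as no roots were moved to medium without one. Of the 302 probe sets raised at least 2-fold at 2 h, 54% differed between the compounds, 134 above NAA and 29 below, but the effect of NAA itself also gives such a difference, and the other 139 were not called different. Against a larger spread hiding an unchanged response, the median ratio of the 6 h to the 2 h log2 fold change over the 388 probe sets was 0.41, also without the 6 h array farthest from the others, and 0.36 with array weights; selection at 2 h inflates the 2 h values and so lowers this ratio, which was 1.3 for NAA. A fading response to naxillin is a biological explanation that stays open as a hypothesis.

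More falls than rises were called with NAA at 6 h, 6677 against 5181. Normalization to equal distributions stays open: rises made up 43.7% of calls as deposited, 49.2% after median centring and 72% after poly-A spike-in scaling, which shifts all probe sets of an array alike and so shows that the balance depends on the reference, not what set it. More mRNA per amount of RNA stays open: the poly-A controls shifted by −0.28 and the hybridization controls by −0.22, a difference of −0.05 (SE 0.06), and the amounts added are not in the labels. The balance of rises and falls is therefore not settled by these arrays, and no biological explanation was tested.

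Deviations of replicates within groups shared 1 axis, with 45.1% of their variance against 10.6% for the next. RNA degradation is argued against by a correlation of −0.07 (permutation p = 0.798) with the 3′ minus 5′ difference of control genes over 15 arrays. Leaf or shoot tissue stays open, with a correlation of −0.88 for the photosynthesis markers (rho −0.85, permutation p = 6e-04, adjusted p = 8e-04, r = −0.85 without the 2 farthest arrays), and so does a difference between experiments, since replicate 3 lay at the same end in all 5 groups (exact p = 0.0239). Sugar or energy state is untested: a list of low-sugar genes lay at the 0.01 percentile of 10000 random lists, but its theme was taken from genes seen on this axis, so that the value cannot count for it, and no biological explanation from the design was tested. The means of the ribosome assembly factors and of the ribosomal proteins followed the axis as closely (r = 0.97 for both, adjusted p = 0.00078), so that the photosynthesis markers do not single out leaf tissue; these genes are among those that define the axis.

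In the contrasts of 3 arrays with 3, 10 splits are too few for a share under 0.05. In each, the real split was the only 1 with as many calls unless stated. The other splits mix both groups, which puts a difference between them into the spread and lowers the calls. Counts of 0 there follow from this construction and do not add support. The real value and the highest of the other splits were 5858 and 0 for NAA 2 h, 11858 and 0 for NAA 6 h, 2402 and 0 for naxillin 2 h, 219 and 2 for naxillin 6 h, 3657 and 0 between compounds at 2 h, 11511 and 0 at 6 h, and 9454 and 0 for NAA 6 h against 2 h. For naxillin 6 h against 2 h they were 520 and 1588, so that 2 of the 10 splits called as many; the larger split follows the shared axis within groups and points to a structure of the samples. For the interaction 2 of 100 splits called as many (6898, highest other 8455). These splits also mix the compounds and the times, so that they cannot test the interaction apart from those differences. The overlap of both compounds gave 2 of 100 at 2 h (1412, highest other 2478) and at 6 h (122, highest other 10235). These splits mix the roots before treatment with those of both compounds, so that they cannot decide whether the responses are alike. The higher counts point to structure, since those splits took all NAA arrays as the reference. Likeness from the shared arrays before treatment is a separate matter. Simulations without effect reached the observed count in 0 of 100 draws at 2 h and 1 of 100 at 6 h. The correlations across probe sets lay below the simulated medians. Neither compound has an effect in these simulations, whose shared count had a median of 0. Neither their counts nor their correlations can therefore decide how alike the responses are. With the arrays before treatment divided between the compounds, a test chosen after the result was seen, 135 to 494 were shared at 2 h and 1 to 94 at 6 h.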

How the results depend on the processing

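Scaling on poly-A controls, the axis covariate, leaving out replicate 3 of every group and dividing the arrays before treatment were chosen only after the result was seen. Signal over background limits dim probe sets. Over all contrasts together, counts moved more than genes. Of the results for named genes with 1 array left out, 2475 kept direction and side of the threshold and 240 were no longer called. The 2475 include results that were not called to begin with. Lost calls included many genes named for naxillin at 6 h, such as AT4G36430, AT4G13580, AT1G72490, AT3G46270 and AT1G19960. Where no construction shows it, the cause was not tested.

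Stricter thresholds call fewer by construction. At least 2-fold were 1422 (NAA 2 h), 4554 (NAA 6 h), 388 (naxillin 2 h), 80 (naxillin 6 h), 1020 and 4523 (between compounds at 2 h and 6 h), 116 (naxillin 6 h against 2 h), 2800 (NAA 6 h against 2 h) and 2902 (interaction), with 172 and 31 shared in direction at 2 h and 6 h. At an adjusted p under 0.01 they were 3481 for NAA 2 h, 778 for naxillin 2 h, 39 for naxillin 6 h, 2158 between compounds at 2 h, 120 for naxillin 6 h against 2 h and 4449 for the interaction.

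The labels do not say that a replicate number marks a shared experiment, and 23 of 30 pairs of the same number in different groups, not all, had deviations correlated above 0.1 (median 0.22, −0.23 to 0.63, against a median of −0.14 for different numbers). As a hint from the data, 11 of 15 arrays correlated best with their own number. With the replicate number as a block, naxillin 6 h had 523 in place of 219, naxillin 6 h against 2 h 1048 in place of 520, and 2143 and 277 were shared at 2 h and 6 h in place of 1412 and 122. The list of wounding, touch and handling genes at naxillin 6 h had an adjusted p of 0.0564 with that block. Array weights gave 2694 for naxillin 6 h and 4579 for naxillin 6 h against 2 h, and only the arrays of the contrast 31 and 44. With poly-A spike-in scaling naxillin 6 h had 389, naxillin 6 h against 2 h 1170 and the shared count at 6 h was 212. The within-group axis as a covariate gave 4509 for naxillin 2 h, 1114 for naxillin 6 h, 5701 between compounds at 2 h, 1914 for naxillin 6 h against 2 h and 2813 and 653 shared. Without replicate 3 of every group there were 856 for naxillin 2 h, 41 for naxillin 6 h, 53 for naxillin 6 h against 2 h and 464 and 23 shared. With an estimated correlation 0 of 39 list calls were left. With the arrays before treatment divided between the compounds, 1 to one and 2 to the other, the medians over 6 divisions were 452 and 30 shared at 2 h and 6 h, partly because each contrast then has fewer arrays.

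Leaving out 1 array gave 4171 to 5467 for NAA 2 h, 10956 to 11254 for NAA 6 h, 1131 to 2219 for naxillin 2 h, 50 to 239 for naxillin 6 h, 2521 to 3518 and 10534 to 11333 between compounds at 2 h and 6 h, 198 to 574 for naxillin 6 h against 2 h, 8226 to 8974 for NAA 6 h against 2 h, 5973 to 7340 for the interaction, and 598 to 1387 and 35 to 135 shared at 2 h and 6 h.

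Values that reversed were small, and all but SCN1 were not called. For NAA 6 h against 2 h, GH3.3 was −0.00 and LBD16 0.01 with quantile normalization once more, and LBD16 was −0.08 to 0.03 leaving out 1 array (0.02 without NAA_6h replicate 1, 0.03 without NAA_6h replicate 3). It was 0.17 with poly-A spike-in scaling and 0.04 without replicate 3 of every group. LBD16 was −0.06 in the interaction, and SCN1, called at 0.31 (adjusted p = 0.0451) between compounds at 6 h, was −0.03, with poly-A spike-in scaling.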

Other observations

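The test of NAA's early genes in naxillin was chosen only after the result was seen; it replaced a set of tests written for a late rise of these genes, which the set did not show. The genes in the next paragraph belong to lists with too few measured members for a test.

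Of 4 auxin synthesis genes measured, 2 fell with NAA. YUC6 fell by 2.25 log2 units at 2 h (SE 0.17, n = 3) and 2.62 at 6 h, and YUC2 by 1.1 and 1.27, while with naxillin YUC6 stood 1.84 and 2.36 above NAA. YUC4 (−0.00, adjusted p = 0.992, and 0.19, adjusted p = 0.0683) and YUC11 (−0.03, adjusted p = 0.837, and −0.05, adjusted p = 0.66) were not called with NAA, and before treatment both lay below the lower quartile of the arrays (4.27 for YUC11). Of the 3 gibberellin receptors, GID1A fell with NAA by 1.44 and 1.46 and GID1C by 0.91 and 1.12, and GID1A fell with naxillin at 2 h by 0.61 (SE 0.10, adjusted p = 0.00251). GID1B stood at −0.05 (adjusted p = 0.81) with NAA at 2 h and was called at −0.32 (adjusted p = 0.0322) at 6 h. That call was lost without NAA_6h replicate 1 (adjusted p = 0.147) or 2 (0.0726), without NPA_0h replicate 1 (0.13) or 3 (0.0859), and under poly-A spike-in scaling (−0.05). WAG2, a kinase gene tied to auxin transport, rose by 1.25 and 1.22 with NAA. Of genes of the vascular tissue, SWEET11, a sucrose transporter, fell by 3.99 (SE 0.52, adjusted p = 1.6e-05) and OPS by 1.75 with NAA at 6 h. CLE26, another phloem gene, rose by 0.74 at 2 h and 0.55 at 6 h (adjusted p = 0.0102), with an adjusted p at 6 h of 0.0507 without NAA_6h replicate 2 and 0.0542 without NPA_0h replicate 2. Regulators of the iron response fell at that time, BHLH101 by 2.55 (SE 0.24) and PYE by 1.51 (SE 0.20). NDB2, an alternative NAD(P)H dehydrogenase of mitochondria, rose with both compounds at 2 h, by 1.78 with NAA and 1.55 (SE 0.14, adjusted p = 6.19e-05) with naxillin, a difference of −0.24 (95% interval −0.53 to 0.06).

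Low-sugar genes, a list written after genes at the end of the shared axis were seen and without those genes, had 11 measured members. With NAA 0 rose and 7 fell at 2 h, or 9 lower adjusted over the list alone (median −0.54, camera adjusted p = 0.00353, adjusted p = 0.468 with an estimated correlation), and 1 rose and 7 fell at 6 h (median −0.86, camera adjusted p = 0.0233, adjusted p = 0.468 with an estimated correlation). With naxillin 0 were called at 2 h (median −0.27, camera adjusted p = 0.0233, adjusted p = 0.468 with an estimated correlation) and at 6 h (median −0.09, camera adjusted p = 0.393).

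A hypothesis was that the genes NAA raises early follow as a set in naxillin by 6 h. For the 175 probe sets raised at least 4-fold by NAA at 2 h, the median change in naxillin from 2 h to 6 h was −0.04 (−0.06 to 0.04 leaving out 1 array), and 99.7% of 10000 random sets had as large a value. Random sets leave out the correlation between genes, and the set test gave p = 0.237 at the preset correlation and p = 0.559 with an estimated one. The hypothesis is therefore left undecided, by a rule changed after these values were known. Against before treatment, the set had a median of 0.35 with naxillin at 2 h (55 called higher) and 0.38 at 6 h (27 called higher). With NAA its medians were 2.57 and 3.14. The set was chosen with the same arrays before treatment, which raises these values. From 2 h to 6 h of naxillin, 14 of the 175 probe sets rose and 24 fell. AT5G17340 (1.97), GH3.1 (1.59), WES1 (1.07) and PUCHI (0.83) were among the rises and MSRB9 (−2.43), XTH18 (−1.72) and UGT73B4 (−0.80) among the falls, chosen after their values were seen.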
